A study of Homo sapiens with 6 samples.

How the data were processed

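RNA from macrophages of 6 human samples was measured on Affymetrix expression arrays, on which a probe set is a group of short probes against 1 transcript. The samples were 3 of macrophages taken from chronic wounds of human subjects (wound macrophages) and 3 of macrophages made from blood monocytes, which the labels call matching (blood-derived macrophages). Groups and replicate numbers were taken from the sample titles. The labels do not say that equal numbers mark 1 donor. They also do not say how many donors each group came from, so p-values measure the spread between these samples.

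The deposited values are on a log scale for 54675 probe sets. Per the submitters' processing notes, GCOS and GCRMA were used, with versions not given in the sources used here. The log2 base is not stated with the deposited values. It was taken as 2 because GCRMA returns log2 values, so every fold below rests on that reading. The deposited log2 values were also centred: the median of each probe set over the 6 samples was 0, with a largest absolute median of 5.0e-07. The processing notes used here do not describe this step. Centring removes the level of each gene and leaves only differences between samples, so no level is given, and a gene close to background cannot be told from a well expressed one. Over all probe sets the array medians lay between -0.046 for wound sample 3 and 0.039 for wound sample 2.

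The filter on low values that had been fixed before the data were examined needs levels and could not be applied, so no filter was used. The planned choice of the probe set with the highest mean of a gene also could not be made. The probe set with the largest SD over all 6 samples, computed without regard to group, was used in its place. An SD over all samples still favours probe sets that differ between the groups. This choice was made before any model was fitted. Gene symbols came from the platform annotation and were updated through gene identifiers, which matched for 41043 of the 41097 probe sets with 1 symbol. A further 1801 probe sets carried several symbols and 11777 had none there, and no gene was named from either kind. After 62 control probe sets and 59 probe sets of X-inactivation and Y-linked genes were left out, 19740 genes were tested, of which 10511 had more than 1 probe set. CD68, chosen beforehand, was not tested because its probe sets carry several symbols. In all, 79 of the 757 genes on the gene lists were not tested.

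Wound and blood-derived macrophages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 samples against 3, no covariate, two-sided), with Benjamini-Hochberg adjustment over the 19740 genes and a threshold of 0.05 on the adjusted p. Errors given with a log2 difference are standard errors from this fit. The 34 gene lists, 21 of pathways and 13 of cell type markers, were fixed before the data were examined. They were tested with camera, which compares the members of a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 34 lists. Each was also tested with an estimated correlation, with fry and with camera on ranks. With an estimated correlation camera also takes its p from the 4 residual degrees of freedom of the fit, which the preset setting does not. Within each list the genes were also adjusted over the list alone. Control probe sets were compared with exact permutation tests of 3 samples against 3, which cannot give a p under 0.1.

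The genes named were chosen by a rule fixed before the data were examined: up to 12 largest rises and 12 largest falls among genes past the threshold with groups that do not overlap, a set of genes around oncostatin M, prostaglandin E2 and macrophage state, and up to 2 rises and 2 falls per list among genes past the threshold. Unnamed clone symbols and genes whose probes depend on inherited alleles were passed over. After the values were seen, the last part was widened to genes past the threshold when adjusted over the list alone, first with up to 6 per list and then with up to 2 rises and 2 falls per list.

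The fit was tested, after it had first been run on the real values, on simulated values for the same 19740 genes, with the within-group SDs of the real probe sets and the same choice of probe set. Of 200 changed genes, 46.3% of those changed by 1 on the log2 scale were recovered, 73.1% of those changed by 2 and 98.5% of those changed by 3, with 6 unchanged genes called. With no change simulated, 0 genes were called and 5.46% had an unadjusted p under 0.05. In the simulation with 200 changed genes, 2 of 40 lists of unchanged genes had a camera p under 0.05. Simulated probe sets were drawn independently, so this does not check lists whose genes vary together. All probe sets of a changed gene were shifted alike, and no structure shared across samples was simulated. The shares recovered and the false calls therefore need not hold for the real genes. For the real immediate-early list the estimated correlation between genes was 0.41. Alternatives planned before the data were examined were 2 other scalings between arrays, the mean of a gene's probe sets, a test of all 54534 probe sets, a variance trend with robust moderation, array weights, the replicate number as a block, and leaving out each sample. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.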

Results

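Wound macrophages had higher expression of 10 genes than macrophages made from blood monocytes. The largest differences were those of PTGS2, the inducible cyclooxygenase that makes the precursor of prostaglandin E2, ATF3, a stress-induced transcription factor, and HBEGF, a growth factor that binds the epidermal growth factor receptor. Oncostatin M (OSM), a cytokine of the interleukin-6 family, was also higher in every wound sample, but did not pass the test over all genes. Immediate-early, NF-kB target and inflammatory cytokine genes were shifted upward as lists under a preset correlation between genes, and not under an estimated one. The gene calls depended on single samples and on the choice of probe set.

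The series title names the induction of OSM by prostaglandin E2, and the comparison the samples give is that of 3 wound with 3 blood-derived macrophage samples. Values are centred log2 values, and a positive difference means higher in wound macrophages.

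PTGS2 (probe set 204748_at) averaged 1.96 ± 0.64 (SD, n = 3) in wound and -1.61 ± 0.20 (SD, n = 3) in blood-derived macrophages, a log2 difference of 3.57 ± 0.32 (SE), or 11.9-fold. ATF3 was higher by 3.26 ± 0.29 (9.55-fold) and HBEGF by 3.11 ± 0.34 (8.61-fold). OSM (probe set 230170_at) averaged 1.62 ± 0.76 in wound and -1.53 ± 0.39 in blood-derived macrophages (SD, n = 3). Its difference was 3.15 ± 0.39 (8.87-fold), with a limma adjusted p over all genes of 0.0624. The other probe set of OSM differed by 1.33, and the mean of its probe sets by 2.24 (limma adjusted p = 0.251).

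Over the 19740 genes, 10 passed the threshold. All 10 were higher in wound macrophages, by at least 2-fold, and 0 were lower, with adjusted p between 0.0334 and 0.0482. Besides PTGS2, ATF3 and HBEGF they were the following. GPR183, an oxysterol receptor that guides immune cell migration, differed by 2.91 ± 0.27. SOCS3, an inhibitor of cytokine signalling through STAT3, differed by 2.65 ± 0.28, and DUSP2, a phosphatase of MAP kinases, by 2.60 ± 0.27. TMEM107, a protein of the base of the cilium, differed by 2.41 ± 0.19, and HES1, a repressor downstream of Notch, by 2.33 ± 0.22. PHLDA2, an imprinted gene, differed by 2.02 ± 0.22, and RASGEF1B, an exchange factor for Ras-like GTPases, by 1.96 ± 0.19. At an unadjusted p under 0.05, limma gave 1147 of the 19740 genes, 670 higher and 477 lower. That share is little above the 5.46% of the simulation with no change. The groups did not overlap for 9.5% of genes, where chance gives 10% for 3 samples against 3.

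The count of 10 rested on few samples and on the choice of probe set. Without blood-derived sample 1 limma called 459 genes, without wound sample 1 it called 3, of which 0 were shared with the 10, and without blood-derived sample 3 it called 10, of which 5 were shared. It called 0 without blood-derived sample 2, without wound sample 2 and without wound sample 3, with 575, 786 and 978 genes at an unadjusted p under 0.05. Each is a smaller share of the genes than the 5.46% of the simulation with no change. With the mean of all probe sets of a gene in place of 1 probe set, 0 genes passed and 831 had an unadjusted p under 0.05, also below that share. The differences were then 1.25 for ATF3, whose probe sets ranged from 0.04 to 3.26, 1.35 for HBEGF, 1.44 for HES1, 1.44 for RASGEF1B, 1.36 for TMEM107, 1.11 for SOCS3 and 0.59 for PHLDA2. PTGS2 stayed at 3.44 (adjusted p = 0.0713), and GPR183 (2.91, adjusted p = 0.0713) and DUSP2 (2.60, adjusted p = 0.0926), with 1 probe set each, lost the call without a change in size. The 10 genes kept a positive difference in all 18 alternatives, from 0.59 for PHLDA2 to 4.21 for PTGS2. The probe sets of HES1 (2 of 3 higher in wound macrophages), HBEGF (2 of 4), SOCS3 (3 of 4) and PHLDA2 (1 of 3) disagreed in sign, and those used for ATF3, TMEM107, HES1 and PHLDA2 are of a type that can match several transcripts.

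**Figure D1:**
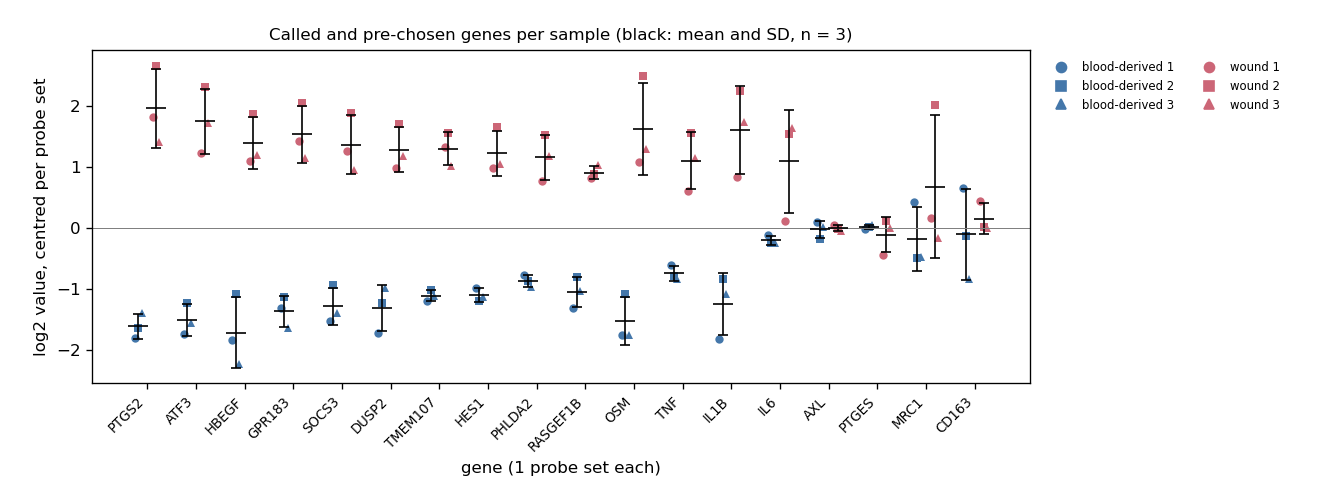
Centred log2 value (vertical axis) of the 10 genes past the threshold, PTGS2 to RASGEF1B, and of 8 genes chosen beforehand, OSM to CD163, in each sample. Symbols mark the samples, blue for blood-derived and red for wound macrophages, with black lines for mean and SD (n = 3). The groups do not overlap for the 10 called genes, OSM, TNF, IL1B and IL6, and overlap for AXL, PTGES, MRC1 and CD163.

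Within the list of oncostatin M and interleukin-6 family cytokines and receptors, 2 of 17 tested genes, SOCS3 and OSM, rose when adjusted over the list alone, and 1 of them, SOCS3, over all genes. The receptor subunits OSMR (-0.23 ± 0.21) and IL6ST (-1.00 ± 0.53) were not called, and the probe sets of IL6ST disagreed in sign. IL6 differed by 1.30 ± 0.39, with a limma adjusted p of 0.555. The list as a whole did not shift (median -0.04, camera adjusted p = 0.178). In the list of prostaglandin E2 synthesis, export, breakdown and receptors, PTGS2 rose and PTGS1, the constitutive cyclooxygenase, fell by 0.70 when adjusted over the list alone, among 13 tested genes. PTGS1 was not called over all genes (adjusted p = 0.419), and 1 of its 4 probe sets was higher in wound macrophages. The terminal synthase PTGES (-0.12 ± 0.19) and the prostaglandin E2 receptors PTGER2 (0.54 ± 0.17) and PTGER4 (0.72 ± 0.29) were not called, and the median of the list was -0.04 (camera adjusted p = 0.92).

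The strongest shifts of lists were in response genes. Immediate-early genes, which cells transcribe within minutes of a stimulus, had a median difference of 1.60, and 16 of 20 tested members were positive. Without blood-derived sample 1 the median was 0.89. Of these 20, 12 rose when adjusted over the list alone and 2, ATF3 and DUSP2, over all genes. EGR1, a zinc finger factor of this class, differed by 3.89 ± 0.50 (adjusted p over all genes 0.0665). NF-kB target genes had a median of 1.09, with 11 of 19 members risen when adjusted over the list alone and 0 over all genes. Among them were CD83 (3.20 ± 0.36), a surface marker of activated antigen-presenting cells, and NFKBIZ (2.45 ± 0.42), a nuclear regulator of NF-kB. Pro-inflammatory cytokines and chemokines had a median of 0.83 (0.50 without wound sample 2 and without wound sample 3), with 8 of 26 risen when adjusted over the list alone and 0 over all genes. They included the chemokines CCL4 (3.57 ± 0.45) and CXCL8 (3.32 ± 0.70) and the cytokines IL1B (2.86 ± 0.40), TNF (1.85 ± 0.25) and IL6. Genes of the cAMP and CREB response, which shares ATF3, NR4A1, NR4A2, DUSP1 and FOSB with the immediate-early list, had a median of 0.59, and 5 of 17 rose when adjusted over the list alone and 1, ATF3, over all genes. NR4A2 (2.43 ± 0.61), an inducible nuclear receptor, was among the 5.

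The camera adjusted p was 7.5e-15 for immediate-early genes, 4.9e-09 for NF-kB targets, 1.9e-08 for cytokines and chemokines and 7.9e-08 for the cAMP and CREB response. For each of these 4 lists the call was lost with an estimated correlation (camera adjusted p = 0.369). The estimates were 0.41, 0.27, 0.06 and 0.27 in that order, so the loss did not follow their size. The preset and estimated settings also differ in degrees of freedom, so the loss cannot be put down to correlation between genes alone. These medians come from 1 probe set per gene, the one of largest SD. Over every probe set they were 0.27 for NF-kB targets, 0.31 for cytokines and chemokines and 0.26 for the cAMP and CREB response.

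In all, 12 of the 34 lists were shifted with the preset correlation, all 12 upward, and 0 with an estimated correlation. Growth and angiogenic factors had a median of 0.12 (0.05 to 0.21 when leaving out 1 sample, adjusted p = 0.0218, and adjusted p = 0.369 with an estimated correlation). Their estimate was -0.02, below the preset 0.01, so a higher correlation was not the reason for the lost call of this list. The test with an estimated correlation also had only the 4 residual degrees of freedom of the fit. HBEGF and EREG (2.69 ± 0.35), both ligands of the epidermal growth factor receptor, were the 2 of 18 members that rose when adjusted over the list alone. For the other shifted lists, no member rose or fell even when adjusted over the list alone. These were T cell markers (median 0.51, or 0.13 over every probe set, adjusted p = 8.8e-04), matrix-degrading proteases and their inhibitors (0.25, up to 0.42 when leaving out 1 sample, adjusted p = 0.00312), lipid uptake, storage and efflux (0.29, with 0.10 to 0.57, adjusted p = 0.0118) and natural killer cell markers (0.39, with 0.19 to 0.64, adjusted p = 0.0316), each with an adjusted p = 0.501 with an estimated correlation. The classical activation markers (0.29, or 0.16 to 0.44 when leaving out 1 sample, adjusted p = 0.0241) had an adjusted p = 0.694 with an estimated correlation. Heat shock and endoplasmic reticulum stress genes (0.24, or 0.04 to 0.50 when leaving out 1 sample, adjusted p = 0.0276) had an adjusted p = 0.785 with an estimated correlation. The TAM receptors, bridging molecules and genes of the uptake of dead cells (0.35, or 0.10 to 0.45 when leaving out 1 sample, adjusted p = 0.0426) had an adjusted p = 0.697 with an estimated correlation. Leaving out 1 sample ended the call at least once for the lists of growth factors, lipid uptake, classical activation, heat shock, natural killer cells and TAM receptors. Testing every probe set ended it for proteases, growth factors, natural killer cells and TAM receptors. Of the TAM list genes chosen beforehand, AXL (0.02 ± 0.16), MERTK (0.35 ± 0.39) and GAS6 (-0.14 ± 0.18) were not called.

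**Figure D2:**
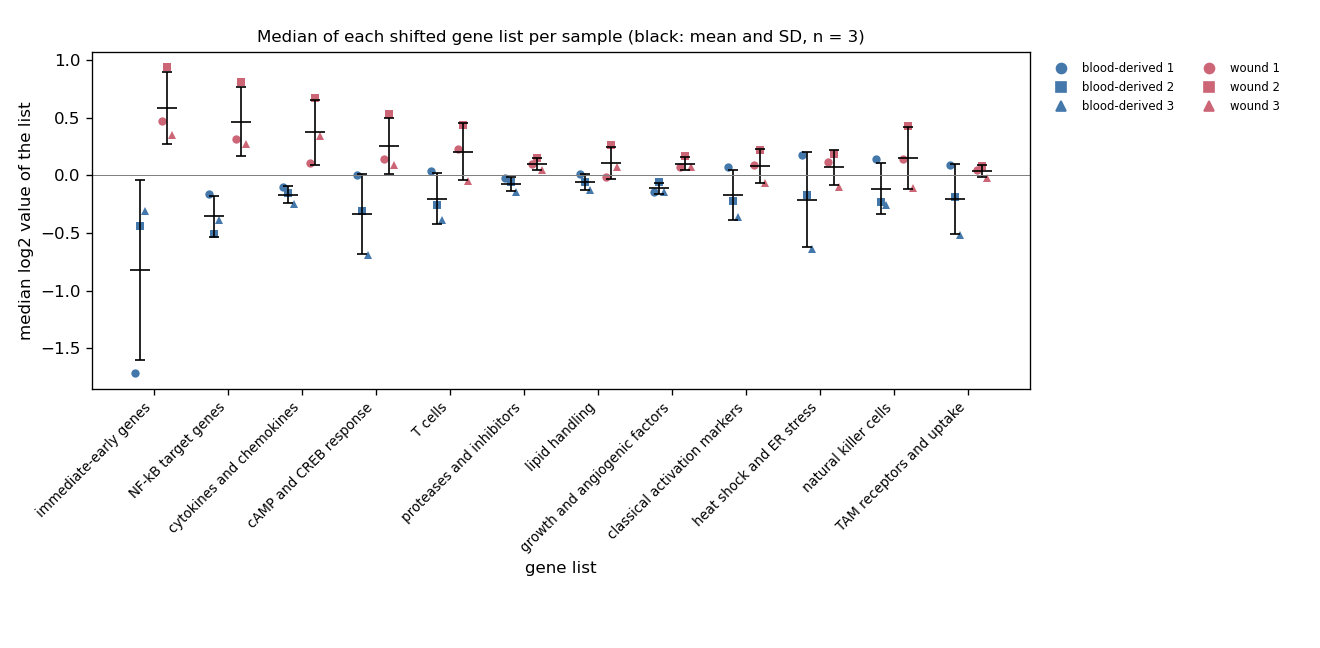
Median centred log2 value (vertical axis) of the members of each of the 12 shifted gene lists in each sample. Symbols mark the samples, with black lines for the mean and SD (n = 3). For immediate-early genes the wound samples lay at 0.35 to 0.94 and the blood-derived samples at -1.72 to -0.31, with blood-derived sample 1 lowest.

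Markers of macrophages themselves did not shift as a list (median 0.18, camera adjusted p = 0.795). MSR1 (0.86 ± 0.21) and MARCO (0.90 ± 0.26), both scavenger receptors, rose and LYZ, the gene of lysozyme, fell by 1.04 when adjusted over the list alone, among 15 tested genes, and none of them passed over all genes. The other probe set of LYZ differed by -0.02. Against blood-derived sample 1 alone the differences were -0.40 for LYZ, 0.84 for MSR1 and 0.63 for MARCO. CD14 (0.18 ± 0.19), CD163 (0.25 ± 0.37) and MRC1 (0.85 ± 0.56) were not called. MRC1 differed by 0.18 without wound sample 2, and CD14 by 0.05 without blood-derived sample 3. The alternative activation markers had a median of 0.12 (adjusted p = 0.214). CCL18 (1.28 ± 0.28), a chemokine of this state, and MSR1 rose and CLEC7A, a receptor for fungal glucans, fell by 1.31 when adjusted over the list alone, among 26 genes. IL10 differed by 0.49 ± 0.19 and was not called. The probe sets of MSR1 and CLEC7A disagreed in sign. Against blood-derived sample 1 alone CLEC7A differed by -0.55 and CCL18 by 1.62. Among 13 blood monocyte markers, CCR2, the receptor that draws monocytes into tissue, fell by 1.55 and VCAN, a matrix proteoglycan, fell by 0.93 when adjusted over the list alone, neither passing over all genes. The list had a median of -0.08 (adjusted p = 0.0571), and 3 of the 5 probe sets of VCAN were higher in wound macrophages. The other probe set of CCR2 differed by -0.11. Against blood-derived sample 1 alone CCR2 differed by -0.96 and VCAN by -1.01.

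The first principal component over all genes did not separate the samples by origin. It held 58.9% of the variance and put blood-derived sample 1 (-41.53) beside wound samples 1 (-23.40) and 2 (-39.05), and blood-derived samples 2 (23.76) and 3 (64.58) beside wound sample 3 (15.64). The second, with 18% of the variance, separated the groups, at -28.52, -26.20 and -1.65 for blood-derived and 19.25, 10.71 and 26.43 for wound samples 1 to 3. The mean Pearson correlation across genes was -0.04 between samples of a group and -0.19 between samples of different groups. Centring lowers such correlations, and genes are not independent replicates. On the control probe sets, blood-derived samples 2 and 3 stood apart. Their 18S ribosomal RNA signal was 2.79 and 2.80, against -0.95 in blood-derived sample 1 and -0.66 to 0.53 in wound samples. Their poly-A spike-ins were -0.79 and -1.14, against 0.08 in blood-derived sample 1. With these 2 samples left out, an alternative chosen after seeing the data, limma called 13 genes, 10 higher and 3 lower, of which 0 were among the 10. With these fewer samples the 10 genes still differed by 1.92 (PHLDA2) to 3.75 (PTGS2), with adjusted p of 0.0524 to 0.196. With a term for them 43 genes were called, 39 higher and 4 lower, and 9 of the 10 were among them. Both alternatives rest on blood-derived sample 1 alone.

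The difference between the 3' and 5' control probe sets, which grows with RNA degradation or incomplete labelling, was larger in all 3 wound samples than in any blood-derived sample. It differed by 1.44 for ACTB (0.57 ± 0.27 in wound and -0.87 ± 0.77 in blood-derived macrophages, SD, n = 3) and by 0.98 for GAPDH (0.53 ± 0.20 and -0.45 ± 0.37, SD, n = 3). The exact permutation p was 0.1 for both, the smallest this design allows. With the ACTB difference as a covariate, an alternative chosen after seeing the data, 8 genes were called, of which 1, DUSP2, was among the 10. The differences of the 10 genes were as large or larger, but their errors grew, from 3.57 ± 0.32 to 4.21 ± 0.52 for PTGS2 (adjusted p = 0.051) and from 3.26 ± 0.29 to 3.79 ± 0.48 for ATF3 (adjusted p = 0.0562). OSM differed by 3.74 ± 0.64 (adjusted p = 0.203). This fit puts 125% of the weight of the blood-derived samples on sample 1, and blood-derived sample 3 counts on the side of the wound samples (weight 0.36). The covariate does not overlap between the groups, so these sizes cannot tell RNA quality from origin.

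**Figure D3:**
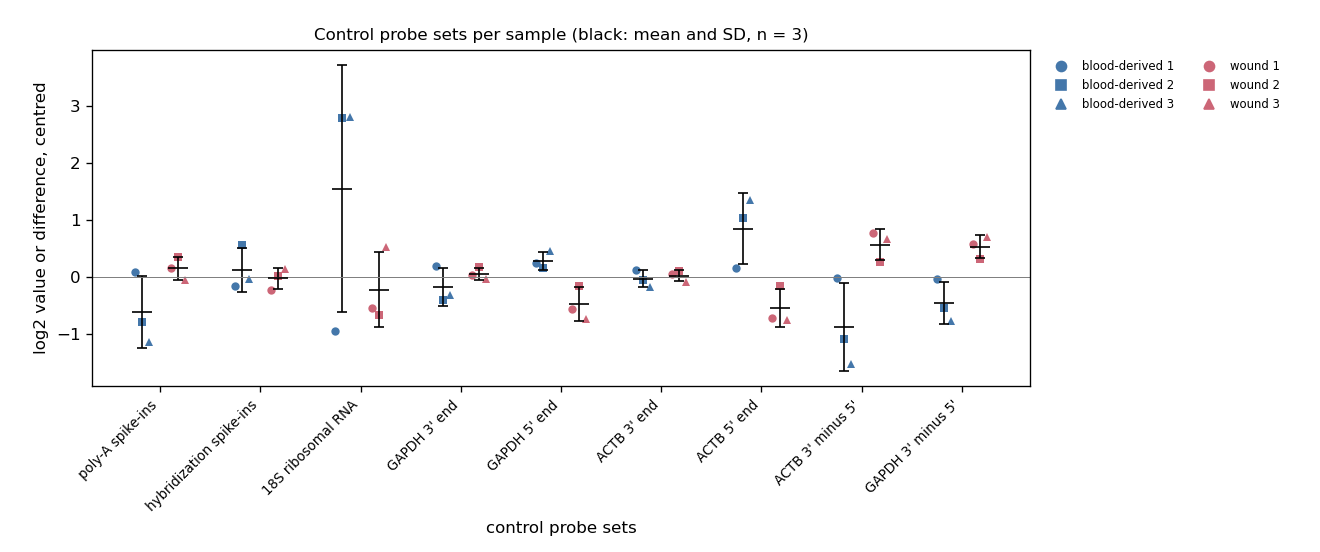
Centred log2 value, or difference of 2 such values, (vertical axis) of each class of control probe sets in each sample. Symbols mark the samples, with black lines for the mean and SD (n = 3). Blood-derived samples 2 and 3 are highest for 18S ribosomal RNA (2.79 and 2.80), and the 3' minus 5' differences of ACTB and GAPDH are higher in each wound sample than in each blood-derived sample.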

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

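The tests of splits of the samples for genes and of a batch were chosen after the results were seen, and the conditions for excluding a batch, on the 18S covariate and on the number of blood-derived samples, were set after its value was seen. The 18S and ACTB covariates were also chosen after seeing the data. The other tests here were set beforehand.

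Outside the gene test, 3 probe sets without a single gene symbol passed the limma test of all probe sets, each higher in all 3 wound samples than in any blood-derived sample. Probe set 234599_at differed by 2.07 ± 0.14 (adjusted p = 0.0354), 244026_at by 2.13 ± 0.19 (adjusted p = 0.0386) and 242712_x_at by 1.62 ± 0.14 (adjusted p = 0.0386). The first 2 had no symbol in the annotation used, and the last carried several. They drew attention as a signal in probe sets that the gene comparison does not use. Samples far from the others of their group were not looked for, since groups of 3 are too small.

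Immediate-early, NF-kB target and inflammatory cytokine genes had a pooled median difference of 1.08 (95% bootstrap interval 0.62 to 1.49 over 64 genes), with an adjusted p = 0.369 with an estimated correlation for each list and 2 members, ATF3 and DUSP2, past the threshold over all genes. The intervals in this paragraph resample genes as if independent, and do not measure the spread between samples. A batch holding blood-derived samples 2 and 3 stays open. The pooled median against blood-derived sample 1 alone was 1.13 (0.59 to 1.55). By list, in the order named, it was 2.05, 0.66 and 0.59, where all samples gave 1.60, 1.09 and 0.83. With 18S as a covariate the list medians were 1.81, 0.80 and 0.72 (camera adjusted p = 0.3, 0.476 and 0.3 with an estimated correlation). All 10 called genes stayed called, but that fit puts 77% of the weight of the blood-derived samples on sample 1. Neutrophils in the wound samples stay open, since the 13 neutrophil markers tested had a median of 0.04 (-0.17 to 0.64), and the interval reaches over the bound of 0.5 set beforehand. In wound sample 2 ADGRG3 was at 4.2, PROK2 at 1.63 and MGAM at 1.31, while BTNL8 was at -0.07 and ALPL at -0.03. A group median does not show a difference confined to 1 sample. A response to the isolation of the wound samples also cannot be told apart from their origin: heat shock and endoplasmic reticulum stress genes had a median of 0.24 (0.14 to 0.49), which spans the bound of 0.25, and isolation goes with group. HSPA1A, HSPA1B and HSPA8 of this list were not tested. Its sample medians overlapped, at 0.18 in blood-derived sample 1 and 0.12, 0.19 and -0.10 in wound samples 1 to 3. RNA quality stays open, since the 3' minus 5' differences (1.44 for ACTB and 0.98 for GAPDH) do not overlap between the groups. With the ACTB covariate the list medians were 2.59, 0.88 and 0.51, and sample 1 has 125% of the weight of the blood-derived samples. The T cell (0.51) and natural killer cell (0.39) lists were higher in wound macrophages, but their sample medians overlapped between the groups. For T cells blood-derived sample 1 was at 0.04 and wound sample 3 at -0.05. For natural killer cells these samples were at 0.14 and -0.11. A state of the cells in the wound itself remains open and untested.

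Splits of the 6 samples into 3 and 3 are too few, at 10, for a share under 0.05. For genes past the threshold, the real split gave 10 and the highest other 1008, and 2 of the 10 splits gave as many. For genes of at least 2-fold, the real split gave 10 and the highest other 461, again 2 of the 10 splits. For shifted lists, the real split gave 12 and the highest other 8, so 1 split of the 10, the real one, gave as many. The split with 1008 genes set blood-derived sample 1 and wound samples 1 and 2 against the others, the parting seen on the first principal component, and points to a structure of the samples other than their origin.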

How the results depend on the processing

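The filter on the 9870 genes of largest SD, the terms for 18S, ACTB and blood-derived samples 2 and 3, and leaving out those samples were chosen after seeing the data. The stricter filter on level was not run because centring removed levels, and the change of pseudocount does not apply to log values. No filter, planned as an alternative, was used throughout. Signal over background cannot be read from centred values. Where no reason is given, the cause was not tested.

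The 10 called genes became 28 with each array centred (27 higher, 1 lower), 52 with quantile normalization (50 and 2), 39 with a variance trend and robust moderation (35 and 4), 63 with 18S as a covariate (57 and 6) and 43 with the batch term (39 and 4). All of the 10 were among these calls, except 1 with the batch term, and all called genes differed by at least 2-fold. The 9870 genes of largest SD gave 140 (114 and 26), also all at least 2-fold, but this filter favours genes that differ between groups. Array weights gave 8162 (4746 and 3416), of which 977 were at least 2-fold, but their estimation did not converge and gave blood-derived sample 2 a weight of 103. With the mean of probe sets both counts were 0. Testing every probe set gave 11 calls, which held 7 of the 10 genes. Leaving out blood-derived samples 2 and 3 assumes that the lone sample varies like the wound samples. Leaving out 1 sample gave 0 to 459 genes and 0 to 444 of at least 2-fold.

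OSM passed the threshold in 8 of 18 alternatives, with a difference of 2.24 to 3.74 and adjusted p from 7.8e-12 to 0.266. It passed with each array centred (3.13, adjusted p = 0.0295), quantile normalization (2.76, 0.00162), the variance trend (3.15, 0.00515), array weights (2.47, 2.7e-04), the replicate block (3.15, 0.00168), the genes of largest SD (3.15, 7.8e-12), 18S (3.21, 0.0176) and without blood-derived sample 1 (3.04, 0.018). The value of 7.8e-12 follows a filter that favours genes that differ between groups. The same difference had a limma adjusted p of 0.0624 without it. The estimation of the array weights did not converge. Leaving out 1 sample gave 2.72 to 3.42.

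The replicate number as a block gave 88 genes (81 higher, 7 lower), all at least 2-fold. The numbers were not shown to pair samples: deviations of equal numbers correlated at 0.28, 0.00 and 0.62, and blood-derived sample 1 correlated best with wound sample 2 (0.49).

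The 12 shifted lists became 0 with an estimated correlation and 0 with fry, and lay between 8 and 16 in the other alternatives, 9 to 15 when leaving out 1 sample. Immediate-early, NF-kB, cytokine and cAMP lists kept the call in 19 of 21 alternatives each, T cells in 18, proteases in 16, growth factors in 14, lipid uptake in 13, classical activation, heat shock and natural killer cells in 11 each and TAM receptors in 7. All alternatives but the estimated correlation and fry used the preset correlation of 0.01, so these counts do not check it. Of the 12 lists, 5 were kept with the ACTB covariate (7 lists shifted up and 1 down), 6 with array weights (7 and 1), 7 with the batch term and without blood-derived samples 2 and 3 (8 and 3 each) and 8 with 18S (9 and 3). Over all alternatives the medians ranged from 0.89 to 2.59 for immediate-early genes, 0.27 to 1.21 for NF-kB targets, 0.31 to 1.26 for cytokines, 0.26 to 0.78 for cAMP, 0.10 to 0.67 for T cells and 0.08 to 0.46 for proteases. They ranged from 0.07 to 0.57 for lipid uptake, 0.04 to 0.29 for growth factors, 0.04 to 0.44 for classical activation, -0.33 to 0.50 for heat shock, 0.01 to 0.68 for natural killer cells and -0.15 to 0.45 for TAM receptors. With the mean of probe sets they were 1.37 for immediate-early genes, 0.82 for NF-kB targets, 0.52 for cytokines and 0.41 for cAMP.

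Reversals were in genes not called and in 2 of the 12 shifted lists, heat shock and TAM receptors. With the batch term and with blood-derived samples 2 and 3 left out alike, the differences became 0.34 for IL6ST, -0.07 for CD14, -0.51 for CD163, -0.47 for MERTK, 0.04 for OSMR and -0.09 for AXL, and the median of heat shock genes -0.16. With 18S they became -0.27 for CD163, -0.27 for MERTK and -0.06 for AXL. With the ACTB covariate they became 0.90 for IL6ST, -0.21 for CD14, -1.05 for CD163, -0.72 for MERTK, 0.05 for PTGES and -0.10 for AXL, with list medians of -0.33 for heat shock genes and -0.15 for TAM receptors. AXL was -0.00 with each array centred and GAS6 0.02 with array weights. Leaving out 1 sample gave -0.06 to 0.07 for AXL (-0.06 without blood-derived sample 2 and -0.01 without wound sample 1), -0.11 to 0.64 for CD163 and -0.23 to 0.04 for PTGES. Over the named genes other than OSM, 581 values kept direction and side of the threshold, 118 newly passed, 79 no longer passed and 27 reversed.

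The 3' to 5' differences moved to 0.58 for ACTB and 0.58 for GAPDH without blood-derived samples 2 and 3, and leaving out 1 sample gave 1.12 to 1.87 and 0.82 to 1.18.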

Other observations

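The 1 test in this part that offers an explanation was set before its result was seen, after MALAT1 had been looked at.

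Single genes moved in lists that did not shift. PFKFB3, an enzyme that drives glycolysis, rose by 1.40 ± 0.26 when adjusted over the list alone, the 1 of 31 hypoxia and glycolysis genes to do so (list median 0.13, camera adjusted p = 0.127). CD74, the invariant chain of antigen presentation, fell by 0.98 when adjusted over the list alone, in a list of 13 class II presentation genes (median -0.14, adjusted p = 0.134). Of the 3 probe sets of CD74, 0 were higher in wound macrophages, but their differences ranged from -0.98 to -0.07. The haemoglobin genes HBB (2.10 ± 0.62) and HBD (0.74 ± 0.21) rose when adjusted over the red blood cell list alone (median -0.06, adjusted p = 0.754). RPS27 rose by 1.52 ± 0.19 when adjusted over the ribosomal protein list alone (median -0.10, adjusted p = 0.112), but its other probe set differed by -0.23. None of these genes passed over all genes.

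Other lists did not shift. Their medians and camera adjusted p were 0.19 and 0.0692 for B and plasma cells, 0.21 and 0.119 for cholesterol biosynthesis, -0.03 and 0.274 for platelets and 0.04 and 0.387 for lysosomal enzymes. They were 0.16 and 0.701 for interferon-stimulated genes, 0.04 and 0.754 for oxidative phosphorylation, -0.03 and 0.754 for endothelial cells and 0.08 and 0.869 for cell cycle genes. They were 0.10 and 0.882 for neutrophils, -0.04 and 0.905 for mast cells and basophils, -0.02 and 0.92 for keratinocytes, 0.03 and 0.959 for fibroblasts and -0.05 and 0.959 for dendritic cells. Median, mean and test differed in sign for the lists of oncostatin M, prostaglandin E2, red blood cells, mast cells, lysosomal enzymes, oxidative phosphorylation, fibroblasts, keratinocytes, platelets and dendritic cells.

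Blood-derived samples 2 and 3 differed from sample 1 over much of the array, and MALAT1, a nuclear RNA chosen after its values were seen, was higher in them on 12 of 12 probe sets, by 0.20 to 6.88. A candidate explanation is a larger share of nuclear RNA in samples 2 and 3. Among probe sets with a large SD (the bound was set beforehand), 64.0% of 2113 without a symbol, but 27.1% of 11025 with 1 symbol, were higher in samples 2 and 3, a difference of 36.9 percentage points (34.7 to 39.1, an interval that treats probe sets as independent). That is the direction this hypothesis needs, but the nuclear RNAs TUG1 (2 of 6 probe sets higher, median -0.19) and MEG3 (5 of 10, median 0.05) did not follow MALAT1, and KCNQ1OT1 leaned the same way on 3 of 5 (median 0.31). A difference in background between arrays could give the same split of probe sets and was not tested, and no biological explanation was tested.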
